A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

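Total RNA was measured by RNA-seq in 8 samples, 4 of NIH3T3 and 4 of HepG2 cells. Libraries were made with a TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and the human genome build GRCh38, without their roles. The mouse build is not given in the sources used here. The authors deposited a table of counts, raw whole-number read counts per gene, and a table of RPKM, reads scaled to gene length and library total, each with 60675 rows under human Ensembl identifiers, per the file headers.

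The NIH3T3 columns of the deposited count table held 47729 rows, after which the next 12946 rows repeated the first 12946 exactly. Of the repeated rows 5855 held counts. No such repeat was found in the HepG2 columns. Across rows, log2 counts of NIH3T3 and HepG2 libraries correlated at r of 0.004 to 0.005 over 16 pairs. The human identifiers therefore do not belong to the NIH3T3 values, which were analysed as 47729 unnamed mouse genes with the repeats left out. The deposited RPKM values were rebuilt from the counts: the authors' divisor changed from row to row in a cycle of 14 rows. Of these 14 divisors, 8 equalled the column totals within 0.01% and 6 equalled no column total, and the origin of these 6 was not determined. Each deposited RPKM value was thus divided by its own library's total in 7.14% of the rows, and divisors differed by up to 1.81-fold. With this cycle, all deposited RPKM values above 1 were rebuilt within 0.1% or 0.001. Gene lengths came from the same relation, whole to within 0.01 bp in all of the 2112 rows checked. Because of the divisors, the deposited RPKM served in alternatives alone. The human lengths behind the NIH3T3 RPKM values do not belong to those genes.

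Groups came from the treatment named in the labels, and replicates were numbered in accession order, which pairs nothing. Per cell line, arsenite was compared with control in edgeR 4.0.16 (R 4.3.3) on the deposited counts, with the default filter on low counts, TMM scaling, the quasi-likelihood test, 2-sided, and Benjamini-Hochberg adjustment at 0.05. Alternatives chosen before the data were examined used DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling, no filter or a mean CPM of at least 5, robust spread, a test against a fold of 1.2, an adjusted p of 0.10, and log2(RPKM + 1) or log2(RPKM + 0.1) in limma with a mean RPKM of at least 0.5 or no filter. Each library was also left out in turn, where a lone sample was assumed to vary like the other group. Fits were tested on simulated counts with 4 sizes of change and independent replicates. Each gene's simulated spread was that of the trend at its abundance, and no simulated library stood apart. In NIH3T3 cells (13124 genes) 8.16%, 35.4%, 86% and 100% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold were recovered, and 4 of the 118 calls were unchanged genes. In HepG2 cells (14184 genes) the shares were 6.12%, 18.4%, 73.5% and 100%, and 7 of the 102 calls were unchanged genes. The common biological coefficient of variation was 0.114 in NIH3T3 and 0.118 in HepG2 cells.

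The rule for genes to name took the 10 highest and 10 lowest log2 fold changes among called genes with a mean CPM of at least 1 and both arsenite libraries on the same side of both controls, and skipped genes without a symbol. The name tables used here list mouse genes, so the human identifiers could not match them (0 did), and the files do not pair identifiers with symbols, so the first 2 identifiers in each direction are printed without names. For the same reason the 32 gene lists and the fixed genes chosen before the data were examined, and the comparison between cell lines through shared symbols, were not run. Floors of 3 counts cover counting error alone. Log2 CPM for principal components and replicate differences used a prior count of 2, and replicate differences were taken over genes with a mean log2 CPM above 3. The length trend of each library was a loess curve with a span of 0.5 over genes with a mean log2 CPM above 1. Cell-cycle identifiers came from scran 1.30.0. Tables were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.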

Results

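RNA was sequenced from 8 samples of 2 established cell lines, NIH3T3 mouse fibroblasts and HepG2 human liver carcinoma cells. Each line was sampled after 24 h with arsenite, the trivalent oxyanion of arsenic, which binds protein thiols, or after 24 h with water as the control. Each of the 4 groups held 2 samples. The labels give 5 nM for the arsenite groups and repeat that figure on the water controls. NIH3T3 cells were at 15 population doublings and HepG2 cells at 25. NIH3T3 libraries held 25994884 and 27563410 counts in the controls and 26576082 and 28444131 with arsenite. HepG2 libraries held 26965049 and 27481613 counts in the controls and 27192636 and 27361110 with arsenite. Libraries of 1 line correlated at Pearson's r of 0.991 to 0.999 across genes on the log2(CPM + 1) scale, and all pairs differed by more than sampling noise. The labels do not say that samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. In HepG2 cells edgeR's fit took each gene's spread from the trend across genes and gave the gene's own replicates no weight. Gene names are not given, because the tables hold identifiers alone, and the identifiers beside the NIH3T3 values do not belong to them.

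In NIH3T3 cells, the comparison of arsenite with water asked which mouse genes changed after 24 h. No gene of the 13300 tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 109 genes had an unadjusted p under 0.05. DESeq2 also called 0 genes, with 39 at an unadjusted p under 0.05, and limma-voom called 0, with 113. Each of these counts lay below a share of 0.05 of the genes tested, which unchanged genes alone would give. The tests were thus cautious here, and 0 calls do not show that arsenite had no effect. The fitted difference exceeded 2-fold for 51 genes, none of them past the threshold. The smallest adjusted p (Benjamini-Hochberg, edgeR) was 0.949. In simulated data with the same library sizes, 86% of genes changed 2-fold and 35.4% of genes changed 1.5-fold were recovered, with replicates drawn independently. No simulated library stood apart and each gene's spread followed the trend with abundance, so these shares may not hold for the real libraries.

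Control 1 stood apart from the other 3 NIH3T3 libraries. It lay at -31.3 on the first principal component, which held 66.1% of the variance, against 10.6 for control 2, 18.9 for arsenite 1 and 1.90 for arsenite 2. Control 2 differed less from arsenite 1 (chi-square over degrees of freedom 3.57) than from its own replicate (29.4). Without control 2, so that control 1 alone stood for the controls, edgeR called 1545 genes, 1470 higher and 75 lower with arsenite. Without control 1 it called 1 gene.

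In HepG2 cells, 4397 of 14389 genes tested (30.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test after arsenite, 1693 higher and 2704 lower. The median change was 1.49-fold among the higher genes and 1.70-fold among the lower genes. Changes above 2-fold were called for 813 genes, 148 higher and 665 lower. The first principal component held 76.9% of the variance and separated the controls, at -42.7 and -22.1, from the arsenite libraries, at 40.4 and 24.4. Scaled to library size alone, 1132 genes were higher and 3318 lower, so that the higher share was 25.4% in place of 38.5%, and the median log2 fold change of all genes was -0.10 in place of -0.02. The count of called genes was 1361 without control 1 (358 higher, 1003 lower), 4504 without control 2 (1666 higher, 2838 lower), 860 without arsenite 1 (215 higher, 645 lower) and 2923 without arsenite 2 (1370 higher, 1553 lower). Of these, 1339, 3881, 852 and 2798 were among the 4397. The higher share ran from 25% without arsenite 1 to 46.9% without arsenite 2. The count above 2-fold was 348 without control 1, 1223 without control 2 and 449 without arsenite 1.

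**Figure D1:**
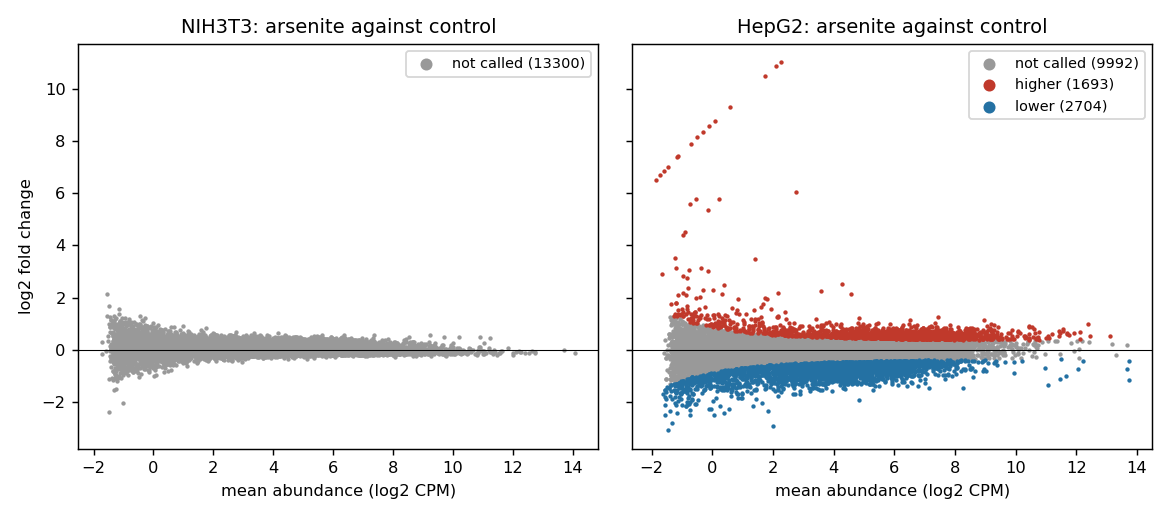
Log2 fold change with arsenite against mean abundance in log2 CPM for each gene tested in NIH3T3 (left) and HepG2 cells (right), from 2 libraries per group. Grey points did not pass an adjusted p of 0.05 in edgeR's test, and red and blue points are the 1693 genes higher and 2704 lower in HepG2 cells; fitted values of genes at 0 in both controls form the rising line of points and are no estimates of fold.

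The rule fixed before the data were examined ordered the HepG2 genes by fitted log2 fold change, and its first higher genes were ENSG00000115461 and ENSG00000164692. With 0 counts in both controls their fold has a lower bound alone, as for 15 genes in all with at least 10 counts in each arsenite library, so which of them rose most was not determined. ENSG00000115461 had 0 counts in both controls and 265 and 237 counts with arsenite, at least 177-fold higher against a floor of 3 counts over the 2 controls (adjusted p = 1.66e-68, edgeR, Benjamini-Hochberg). ENSG00000164692 had 0 counts in both controls and 258 and 194 with arsenite, at least 159-fold higher against the same floor (adjusted p = 6.99e-65, edgeR, Benjamini-Hochberg). These levels were low, 9.49 ± 0.90 and 8.55 ± 1.85 CPM with arsenite (SD, n = 2). Both belonged to a group of 23 genes with at most 3 counts over the 2 controls and at least 10 counts in each arsenite library, all 23 of them called. Together the 23 genes took 9 and 7 counts in the controls and 1377 and 1144 counts with arsenite, and 1 gene showed the opposite arrangement. RNA from another source in both arsenite libraries could give such counts too, so these values do not show that arsenite raised these genes.

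The first lower genes by the same rule were ENSG00000197149 and ENSG00000231607. ENSG00000197149 fell from 6.79 ± 2.27 to 0.888 ± 0.095 CPM (SD, n = 2), with 142 and 240 counts in the controls and 25 and 22 with arsenite. Its log2 fold change was -2.93 (SE 0.28), 7.62-fold lower, with an adjusted p of 3.77e-23 in edgeR's test (Benjamini-Hochberg). ENSG00000231607 fell from 83 and 30 counts in the controls to 10 and 10 counts with arsenite, with a log2 fold change of -2.41 (SE 0.37), 5.32-fold lower (adjusted p = 7.92e-09, edgeR, Benjamini-Hochberg). Without control 1 its log2 fold change was -1.46 (adjusted p = 0.042, edgeR, Benjamini-Hochberg); over 15 alternative settings the adjusted p ran from 1.46e-11 to 0.326. With the deposited RPKM and no filter on low values, no HepG2 gene passed, these 4 included.

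The HepG2 genes that changed differed by abundance and by length. Of 5 equal groups of genes ordered by abundance, the most abundant held 782 higher and 350 lower genes, the middle group 236 higher and 793 lower, and the least abundant 137 higher and 320 lower. Genes called lower had a median length of 5552 bp and genes called higher 4046 bp, against 4467 bp for all genes tested. Of 10 equal groups ordered by length, that of the longest genes held 93 higher and 429 lower genes, and that of the shortest 148 higher and 207 lower. With the length trend of each library removed, a step that also takes out any trend shared by a group, the order of the median lengths reversed, to 4714 bp for the lower and 5253 bp for the higher genes. Length trends, taken on log2 CPM relative to the mean of the 4 libraries, differed within the groups. Spearman's rho with gene length across genes was -0.243 in arsenite 1 and 0.066 in arsenite 2.

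**Figure D2:**
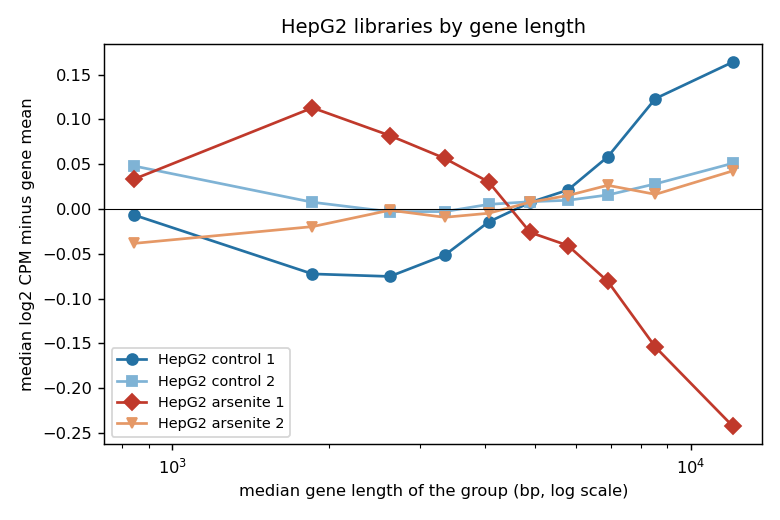
Median log2 CPM of each HepG2 library, relative to the mean of the 4 libraries, in 10 equal groups of genes ordered by length (median length in bp, log scale). Blue lines are the 2 controls and red and orange lines the 2 arsenite libraries; in the group of the longest genes control 1 lay at 0.16, control 2 at 0.05, arsenite 1 at -0.24 and arsenite 2 at 0.04.

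More rows held counts in the HepG2 controls, 22540 and 22691, than in the arsenite libraries, 21787 and 22167. The 10 most abundant genes took 11.3% and 10.4% of the counts in the HepG2 controls and 8.53% and 9.58% with arsenite. In NIH3T3 cells these shares overlapped, at 8.20% and 7.50% in the controls and 7.20% and 7.75% with arsenite. Whether the arsenite effect differed between the cell lines was not tested, because the files pair no mouse gene with a human gene.

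**Figure D3:**
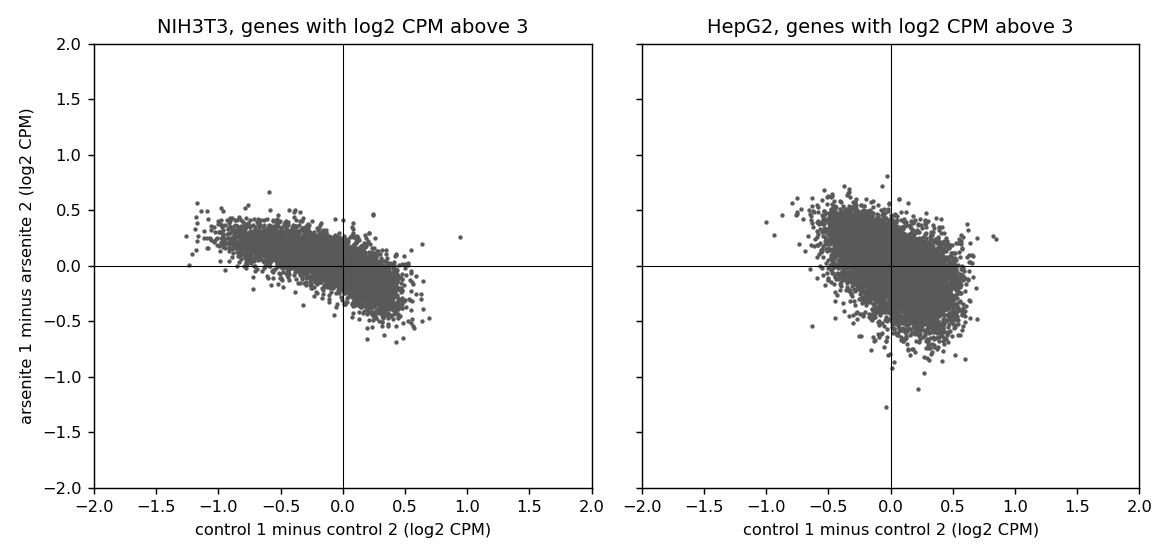
Difference in log2 CPM between the 2 arsenite libraries (vertical axis) against the difference between the 2 controls (horizontal axis) for each gene with a log2 CPM above 3, in NIH3T3 (left) and HepG2 cells (right). The differences come from separate libraries and correlated across genes at r = -0.751 in NIH3T3 and -0.555 in HepG2 cells, and the sign depends on the arbitrary numbering of the replicates.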

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

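The own-total RPKM, length and repeated-row settings were chosen after seeing the data. Among the NIH3T3 alternatives, the test against a fold of 1.2 and the adjusted p of 0.10 could call no gene. The smallest adjusted p of the main edgeR fit there was 0.949 (Benjamini-Hochberg). The settings with deposited RPKM carried its changing divisors. In NIH3T3 cells, 16 of 18 alternatives also called 0 genes, and leaving out 1 library gave 0 to 1545, the highest without control 2 and 1 without control 1. In HepG2 cells, 12 of 19 alternatives stayed within 1.5 times the 4397 genes. A test against a fold of 1.2 called 2498. The deposited RPKM gave 912 with a pseudocount of 1, 869 with 0.1 and 0 without a filter (3833 at an unadjusted p under 0.05, limma), and RPKM divided by each library's own total gave 3311. Leaving out 1 library gave 860 (without arsenite 1) to 4504 (without control 2); it gave 1361 without control 1 and 2923 without arsenite 2, where fewer samples entered. The cause was not tested for the unfiltered RPKM. The 813 genes above 2-fold became 495 in DESeq2, 370 with a mean CPM of at least 5, where fewer genes were tested, 329 with the deposited RPKM and a pseudocount of 1 (780 with 0.1), 0 without its filter and 181 with own-total RPKM and a pseudocount of 1. ENSG00000115461 and ENSG00000197149 kept their call in 17 of 18 settings that tested them, and ENSG00000164692 and ENSG00000231607 in 14 of 15. All 4 kept their direction and lost the call with the unfiltered RPKM (adjusted p 0.299 to 0.326, limma). Alternatives fixed beforehand for the gene lists, the shared fit of 8 libraries and the comparison of cell lines were not run, for want of symbols.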

Other observations

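All tests in this part were chosen after the results they bear on were seen, and so were the limits that decide them. Cell-cycle genes were examined in HepG2 cells as a hypothesis, that arsenite shifted cells between phases. Of 113 G1 identifiers tested 14 were higher and 25 lower, of 116 S identifiers 24 were higher and 26 lower, and of 110 G2M identifiers 16 were higher and 28 lower. None of the sets was called by camera with a preset correlation of 0.01, at adjusted p of 0.870, 0.870 and 0.988, or with an estimated correlation, at adjusted p of 0.988, 0.812 and 0.988. The 95% bootstrap intervals of the median log2 fold change ran from -0.16 to 0.02, -0.07 to 0.21 and -0.08 to 0.13. The bootstrap resampled the genes of each set as if independent and left out the spread between libraries. The intervals may thus be too narrow and do not bound the arsenite effect. Even so they were too wide to exclude a small shift.

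In both lines the replicate differences correlated across genes. The difference between the controls correlated with that between the arsenite libraries at r = -0.751 in NIH3T3 and -0.555 in HepG2 cells. In 100 simulations, which drew genes as well as replicates independently, r stayed between -0.028 and 0.027. Genes that vary together could also give a large r, and the simulations held none. They thus do not show how unusual the real values are. Gene length in HepG2 cells is argued against, since r was -0.556 with the trend of each library removed. Unequal depth had little room to act, since the totals were nearly equal beforehand. For the same reason thinning could change little, so r of -0.746 and -0.554 after thinning adds no evidence. Without the 100 most abundant genes r was -0.739 and -0.547. These were too few of the genes to move r much, so a role of abundant genes cannot be told from this step. The replicate differences predicted 77.4% of the variance of the group difference in NIH3T3 and 51.7% in HepG2 cells. The simulations gave at most 0.124% and 0.168%, again with independent genes, so they set no limit for genes that vary together. Moreover, 1 outlying library enters both sides, so the real values do not settle how much of the HepG2 difference is shared variation. The real grouping called 4397 genes and the other groupings of the 4 libraries 0 at most; it was 1 of 3 groupings, too few to give a share under 0.05.

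The greater length of the genes called lower in HepG2 cells may come from length trends of single libraries. The trend between the 2 arsenite libraries, a Spearman's rho of 0.345 in size, exceeded the largest between groups, 0.203. Arsenite 1 minus control 1 gave a rho of -0.203 and arsenite 1 minus control 2 gave -0.181. Arsenite 2 minus control 1 gave -0.075, and arsenite 2 minus control 2 gave 0.017. The lower genes were still the longer ones without arsenite 1 (5113 against 3926 bp) and without control 1 (5428 against 3049 bp). The same held without control 2 (5691 against 4050.5 bp) and without arsenite 2 (6399 against 3718.5 bp). Length bias as the whole cause of the calls is argued against, since 91.99% of them, 4045 genes, were kept with the same sign once the trend was removed. An effect of arsenite on long genes stays open and untested.

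The 23 HepG2 genes near 0 counts in both controls may mark RNA from another source in both arsenite libraries, or genes that arsenite switched on. A single source would keep their counts in 1 ratio between the arsenite libraries: their summed CPM stood in a ratio of 1.23, and the chi-square test of the counts gave p = 0.157. The chi-square was 28.6 for the 23 genes and 35.0 at the median of 10000 random lists matched on counts. Of these lists 26.5% were at least as even, so ordinary genes can pass this test too. These counts thus do not tell the explanations apart, and what the genes are, which could bear on this, was not examined. With other count limits 11 to 23 genes met the definition.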
